A study of Solanum lycopersicum with 86 samples.

How the data were processed

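RNA was sequenced from the first internode of young tomato plants (Solanum lycopersicum), the stem segment between the cotyledons and the first true leaf, and from its pith, the innermost tissue of that segment. The whole internode samples contain pith. Plants of the cultivars Moneymaker and M82 were grown at 20 °C, 70% humidity and a 16/8 h light/dark cycle. They then stayed in white light (WL, 200 PAR of photosynthetically active radiation) or received the same white light with added far-red light (FR), which lowered the ratio of red to far-red light to 0.21. Internodes were harvested 6, 24, 30 and 48 h after the treatment started, and pith at 30 and 48 h.

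There were 86 libraries in 24 groups of cultivar, light, tissue and time, with 2 to 6 libraries per group, 46 from Moneymaker and 40 from M82. The labels call the samples biological replicates and state at least 4 per group, and the groups analysed here hold fewer in some cases. Groups were taken from the sample titles. One treatment field disagreed with them: all white light Moneymaker samples carry the FR tag there, while their titles and sample codes give white light. The titles were used.

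Libraries were made from polyA RNA with random primers, per the labels' protocols. FastQC, Trim Galore, STAR and featureCounts are named in the submitters' processing notes, without versions. The genome build, the annotation and the strand setting are not given in the sources used here. The deposited table holds a signal per gene and library: read counts that the authors scaled by 1 factor per library. Within a library every value was a whole multiple of the value of 1 read. Of the nonzero values below 2000 reads, 100% came out whole within 0.02 of a read, in all 86 libraries. How the factors were chosen is not given in the sources used here. The recovered depth was 0.769 to 22.1 M reads in listed genes per library, with a median of 2.98 M, and 16801 to 22687 genes had at least 1 read. Sums of the deposited values ran from 834614 to 1334743 per library. No column lacked a sample, and no row lacked a gene identifier.

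The table lists 23050 genes by Solyc identifier. None of these matched the reference gene table (0 matches), so no gene names are given and no more than 2 rising and 2 falling identifiers are printed per comparison. They were chosen by smallest p among genes with an adjusted p below 0.05; for light and tissue comparisons they also needed at least a 2-fold change and a mean log2 value of at least 1. This rule was fixed before the data were examined. Lists of pathway genes by name were also fixed then and could not be applied. Gene groups were instead defined in one cultivar and tested in the other, which by the labels shares no library with it. Genes with near-identical copies or overlapping antisense partners cannot be told apart from the table.

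The planned main test was a count model, the quasi-likelihood F-test of edgeR, but the deposited values are not counts. The 19029 genes with a mean value of at least 1 were therefore tested on log2(value + 1) with limma 3.58.1 (trend and robust moderation) in R 4.3.3, in 1 fit of all libraries with a mean for each of the 24 groups. Fold changes are on this scale and understate the change of low genes. All adjusted p-values of single genes are Benjamini-Hochberg values from this fit, and a gene was called at an adjusted p below 0.05. Light effects were tested at each tissue and time and as means over times. Interactions of light with cultivar, tissue and time, the difference between pith and internode, and the difference between cultivars under white light were tested in the same fit. The difference between clock times (6 and 30 h against 24 and 48 h) was added after seeing the data, as were the gene groups and all checks of labels.

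Gene groups were tested with camera, which compares a group with all other genes, at a preset correlation, with an estimated correlation and with a replicate block, and with fry; values were adjusted over the 32 tests. A light score was computed for each library as the mean log2 value of the genes higher under FR minus that of the genes lower under FR, with both lists called in internodes of the other cultivar. Its differences were tested by exact two-sided permutation, or for means over times by 100000 permutations within times, and adjusted over 16 tests. These permutations ignored the replicate numbers described next.

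The replicate number marks plants of 1 batch, per the series design, so numbers pair samples by label. In Moneymaker internodes at 48 h, the highest replicate numbers carry sample codes with lower numbers. They were kept as separate batches, which may not follow the plants there. Residuals of FR and WL libraries with the same number in 1 cultivar, tissue and time had a mean correlation of 0.05 over genes (26 pairs), against -0.0086 for other numbers. Libraries of 1 cultivar and light from other tissues or times gave 0.12 with the same number (142 pairs) and -0.026 otherwise. The fit with this block is an alternative. Other alternatives were size factors instead of the authors' scaling, no filter, a fit of the compared groups alone, DESeq2 1.42.0, and each library left out in turn. Alternatives added after seeing the data were edgeR 4.0.16 on the recovered reads, a pseudocount of 0.25, and leaving out libraries whose expression went against a label. The edgeR test is the one planned as the main test for counts, run here with the authors' scaling.

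No 2 libraries of a group agreed within sampling noise: over 125 pairs, chi-square per degree of freedom ran from 2 to 104. The fit was tested on simulated reads at the real depths for 19029 genes, with 100 genes changed at each fold. For the Moneymaker internode mean it recovered 77% of genes changed 2-fold and 100% of those changed 4-fold. For the M82 pith mean the shares were 48% and 91%, and for the M82 internode at 24 h, with 2 libraries against 2, they were 1% and 51%. The changed genes were drawn from the more highly expressed ones, so these shares do not cover the lowest genes tested. Of the genes called, 2.75%, 6.08% and 5.45% were unchanged ones, in that order. The simulation held no batches and no wrong labels. Figures were drawn with matplotlib 3.10.9.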

Results

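The response of the tomato stem to added far-red light (FR), a signal of neighbouring plants, was compared with white light (WL) in the cultivars Moneymaker and M82. Messenger RNA was sequenced from whole first internodes at 6, 24, 30 and 48 h after the treatment started, and from their pith at 30 and 48 h. Moneymaker internodes gave 19 FR and 13 WL libraries and its pith 8 and 6. M82 internodes gave 11 FR and 15 WL libraries and its pith 5 and 9. Single groups of cultivar, light, tissue and time held 2 to 6 libraries. Depth ran from 0.769 to 22.1 M reads in listed genes, with a median of 2.98 M. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 among 19029 genes, and 951 genes would pass an unadjusted p of 0.05 by chance. Fold changes are on the log2(value + 1) scale and are given ± SE.

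In Moneymaker internodes, averaged over the 4 times, 139 genes were higher and 163 lower under FR than under WL (19 and 13 libraries). Of these, 61 and 64 differed by at least 2-fold. Solyc06g035530 rose from a mean log2 value of 1.37 under WL to 4.88 under FR, a log2 fold change of 3.52 ± 0.33 (11.4-fold, adjusted p = 1.2e-12). Solyc06g060830 rose by 1.95 ± 0.17 (3.87-fold, adjusted p = 7e-14). Solyc02g085020 fell from 8.05 to 5.07, a change of -2.99 ± 0.33 (adjusted p = 2e-09), and Solyc04g050625 changed by -2.99 ± 0.35 (adjusted p = 2.5e-09). The count fell to 161 without the white light library at 6 h with replicate number 2, 1 of only 2 libraries in its group.

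In M82 internodes, 56 genes were higher and 80 lower under FR (11 and 15 libraries), 38 and 41 of them by at least 2-fold. Solyc05g008240 rose from a mean log2 value of 0.417 to 3.74, a change of 3.32 ± 0.34 (adjusted p = 9.6e-11). Solyc06g035530 rose by 3.33 ± 0.36 (10.1-fold, adjusted p = 7e-10). Solyc12g088170 fell from 7.82 to 4.17, a change of -3.66 ± 0.45 (adjusted p = 4.4e-08), and Solyc02g085020 changed by -3.39 ± 0.37 (adjusted p = 1.5e-09). The total of 136 genes fell to 68 without the FR library at 24 h with replicate number 2, and to 90 without the WL library at 24 h with replicate number 1.

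The far-red genes of one cultivar moved the same way in the other, and by their labels the cultivars share no libraries. Of the 56 genes higher under FR in M82 internodes, 44 were called higher in Moneymaker internodes, and the whole list had a median log2 fold change of 1.36 there. Of the 80 lower genes, 54 were called lower there, and the whole list had a median of -0.888. Independent lists would share 0.41 higher and 0.69 lower genes. In the reverse direction, the 139 higher genes of Moneymaker had a median of 0.61 in M82 internodes and 132 of them had the same sign. The 163 lower genes had a median of -0.655, and 162 had the same sign. All 4 list tests held with an estimated correlation between genes (camera adjusted p = 1.8e-08 or below). Log2 fold changes in the cultivars correlated with r = 0.487 across all genes tested, which are not independent replicates. Of the libraries labelled M82 WL internode, 4 expressed Moneymaker genes, as described at the end. Without the 12 libraries that went against a cultivar or time label, 36 higher and 59 lower genes were called in internodes of both cultivars, against 0.38 and 0.68 for independent lists.

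A light score summarised these genes in each library: the mean log2 value of the genes higher under FR minus that of the genes lower under FR, both taken from internodes of the other cultivar. In Moneymaker internodes it was 0.73 ± 0.41 under FR (SD, n = 19) and -1.68 ± 0.22 under WL (SD, n = 13). The difference over times was 2.46 (permutation p = 1e-05, the smallest possible, and adjusted p = 0.00016). All permutations of the light score treated libraries as independent, although the replicate number marks a batch of plants. In M82 internodes the score was 0.49 ± 0.6 under FR (SD, n = 11) and -1.17 ± 0.6 under WL (SD, n = 15), a difference of 1.64 (permutation p = 2e-05, adjusted p = 0.00016). In pith it was 0.76 ± 0.38 against -1.87 ± 0.06 in Moneymaker (SD, n = 8 and 6, permutation p = 0.00091, adjusted p = 0.0049). In M82 pith it was 0.88 ± 0.23 against -1.08 ± 0.43 (SD, n = 5 and 9, permutation p = 0.0013, adjusted p = 0.0051). Pith at 30 and 48 h allows few distinct splits, 35 and 35 in Moneymaker and 15 and 56 in M82. Its p therefore cannot fall as low as in internodes, and these p-values do not rank the tissues.

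At each tissue and time in Moneymaker, every library titled FR scored above every library titled WL. This includes the 19 libraries whose titles give white light while a treatment field gives FR. The Moneymaker differences were 2.57, 2.71, 2.67 and 1.88 in internodes at 6, 24, 30 and 48 h (exact permutation p = 0.048, 0.018, 0.029 and 0.0048, each the smallest possible). In M82 internodes they were 2.05, 1.08, 1.8 and 1.61 (exact permutation p = 0.029, 0.33, 0.054 and 0.029). At 24 h in M82, the FR libraries scored 0.71 (replicate 2) and -0.97 (the library labelled replicate 3), the latter close to the WL libraries at -1.33 and -1.08. Each split of 2 libraries against 2 has a mirror image, so 0.33 is the smallest p possible there. At 30 h in M82 the library labelled WL replicate 1 scored 0.82, among the FR libraries. Adjusted over 16 tests, p was 0.059 for Moneymaker at 6 h, 0.33 for M82 at 24 h, 0.061 for M82 at 30 h and at most 0.038 for the other internode times. In pith at 30 and 48 h the differences were 2.87 and 2.4 in Moneymaker (exact permutation p = 0.029 each, adjusted p = 0.038 each). In M82 pith they were 2.05 and 1.88 (exact permutation p = 0.067 and 0.018, adjusted p = 0.071 and 0.038), and 0.067 is the smallest p possible at 30 h.

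**Figure D1:**
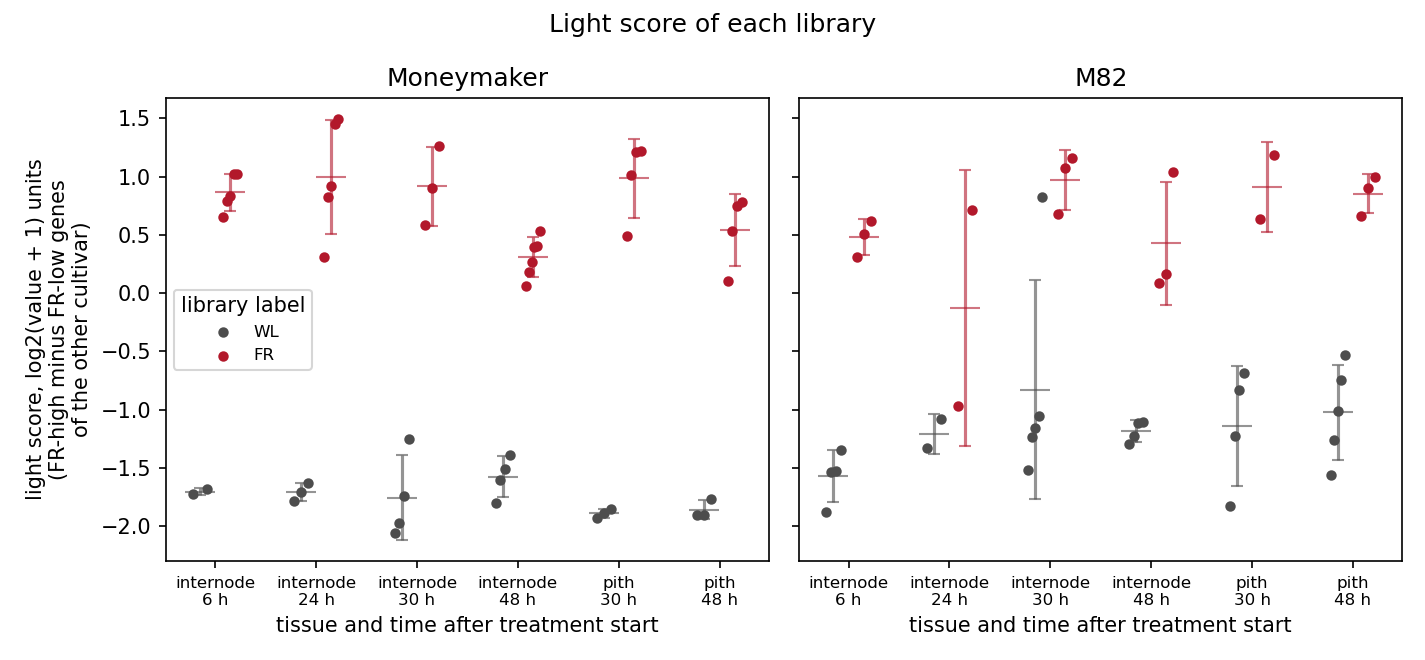
Light score of each library (points, log2(value + 1) units) by cultivar, tissue and time, red for FR and grey for WL, with horizontal marks for group means and bars for SD. FR libraries lie above WL libraries in each group pair except M82 internodes at 30 h, where 1 WL library lies at 0.82.

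Single times gave fewer calls than the means over times in the main fit, and Solyc06g035530 already differed at 6 h in both cultivars. In M82 internodes this order turned at 6 h with DESeq2, and at 30 h without the 12 libraries that went against a label, as given below. Solyc06g035530 was called higher in Moneymaker internodes at each time, by 3.85 ± 0.74, 3.86 ± 0.64, 2.9 ± 0.67 and 3.45 ± 0.57 at 6, 24, 30 and 48 h. In M82 it was called at 6, 30 and 48 h, by 4.22 ± 0.67, 3.08 ± 0.64 and 3.81 ± 0.67, while the value at 24 h was 2.21 ± 0.88 (adjusted p = 1), with values of 0 and 38.1 in the 2 FR libraries and 0.317 and 0.387 in the 2 WL libraries. Solyc02g085020 was called lower in Moneymaker at 24 and 30 h, by -3.41 ± 0.65 and -3.84 ± 0.68, and in M82 at 6 and 30 h, by -3.48 ± 0.68 and -4.96 ± 0.65. Moneymaker internodes had 5, 18, 27 and 30 genes called at the 4 times, and M82 internodes 52, 0, 72 and 6. For the 0 in M82 at 24 h with limma, 710 genes had an unadjusted p below 0.05, DESeq2 called 1 gene and edgeR called 0. With a replicate block the counts were 8 and 52 in Moneymaker at 6 and 48 h, and 95 and 10 in M82 at 6 and 48 h. These single-time counts depended on single libraries, as at 6 h in M82, where 1073 genes were called without the WL library with replicate number 3, which had 12.9 M reads.

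Solyc05g053530 was called higher under FR at 6 h in both cultivars and at none of the later times. Its log2 fold change at 6 h was 3.95 ± 0.43 in M82 (adjusted p = 2e-09) and 3.07 ± 0.47 in Moneymaker (adjusted p = 0.00018). At 24, 30 and 48 h it was 0.16 ± 0.57, 0.4 ± 0.41 and 0.24 ± 0.43 in M82, and 0.04 ± 0.41, 0.07 ± 0.43 and 0.23 ± 0.37 in Moneymaker. Its value was 0 in every WL library at 6 h, against 5.16 to 25 under FR in M82 and 2.84 to 13.1 in Moneymaker. The Moneymaker comparison at 6 h rests on 2 WL libraries. It had 511 genes at an unadjusted p below 0.05, where chance gives 951, and edgeR shared 1 of its 5 calls. Of the 4 M82 WL libraries at 6 h, replicates 1 and 5 expressed Moneymaker genes. Solyc02g089350 was 3.3 ± 0.48 higher at 6 h in M82 (adjusted p = 1.4e-05), and its values there at 24, 30 and 48 h were -0.12 ± 0.63, 1.54 ± 0.46 and -1.01 ± 0.48. These were the 2 genes whose FR effect differed between the 4 times in M82 internodes (adjusted p = 0.00025 and 0.0012), where DESeq2 called 18 genes and edgeR 1. A pseudocount of 0.25 left 1 gene and a fit of the compared groups alone 0, and 13 of 100 splits of the libraries, the real one included, gave at least 2. In Moneymaker internodes limma called 0 genes in this test, with 596 at an unadjusted p below 0.05 and 0 by both DESeq2 and edgeR, and 1 with a replicate block.

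**Figure D2:**
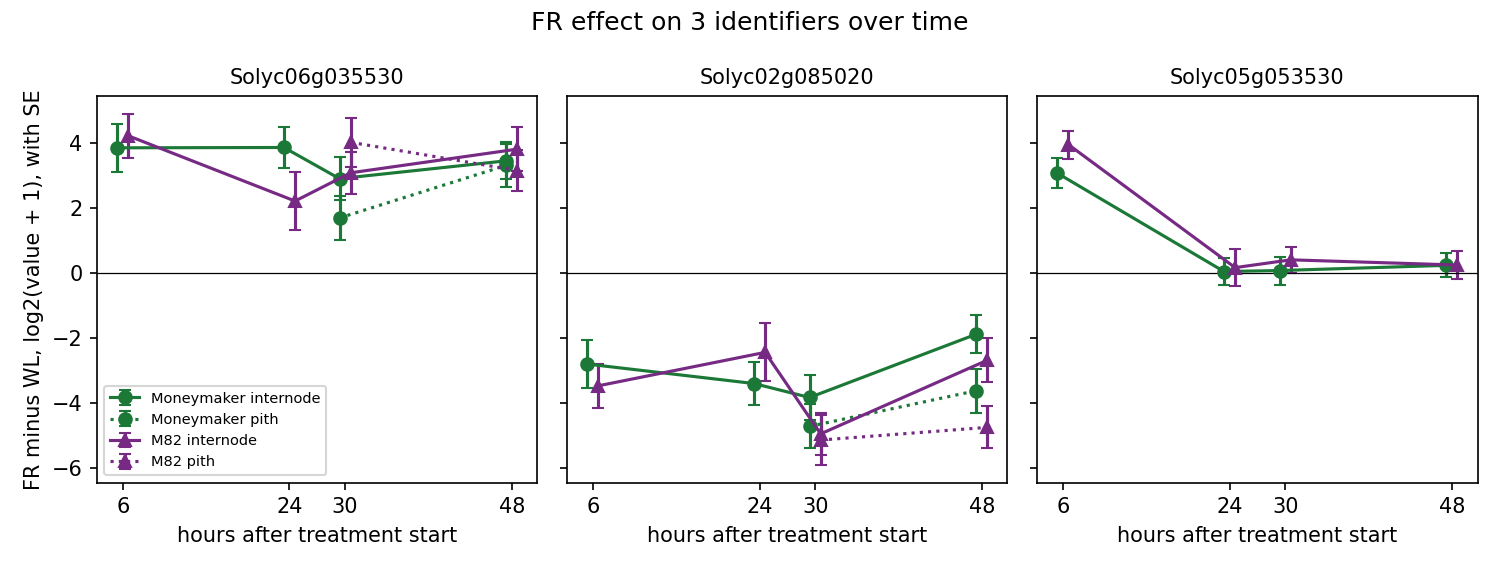
Log2 fold change between FR and WL (points, bars are SE) against hours after the treatment started for 3 genes, green circles for Moneymaker and purple triangles for M82, solid lines for internode and dotted lines for pith. The values of Solyc06g035530 lie above 0 and those of Solyc02g085020 below 0 at all times plotted, and Solyc05g053530, plotted for internodes, is at 3.95 and 3.07 at 6 h.

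In Moneymaker pith, 35 genes were higher and 61 lower under FR (8 and 6 libraries), 34 and 53 of them by at least 2-fold. Solyc06g060830 rose by 2.02 ± 0.25 (4.07-fold, adjusted p = 4.1e-08), and Solyc01g110790 rose from a mean log2 value of 1.71 to 4.12, a change of 2.41 ± 0.37 (adjusted p = 1.3e-05). Solyc02g085020 fell from 7.53 to 3.35, a change of -4.18 ± 0.48 (adjusted p = 4.1e-08), and Solyc05g053550 fell from 7.83 to 4.63, a change of -3.2 ± 0.41 (adjusted p = 6.4e-07). At 30 h 46 genes were called and at 48 h 14. The 96 genes of the mean became 59, 63 and 54 without the WL library at 48 h replicate 4, at 48 h replicate 6 and at 30 h replicate 5, in that order.

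In M82 pith, 433 genes were higher and 273 lower under FR (5 and 9 libraries), 166 and 161 of them by at least 2-fold. Solyc06g035530 rose from a mean log2 value of 1.09 to 4.67, a change of 3.58 ± 0.5 (adjusted p = 1.3e-06), and Solyc06g060830 rose by 2.01 ± 0.26 (adjusted p = 2e-07). Solyc02g085020 fell from 6.67 to 1.72, a change of -4.95 ± 0.51 (adjusted p = 5.1e-10), and Solyc09g065100 fell from 3.94 to 0.467, a change of -3.47 ± 0.44 (adjusted p = 2e-07). At 30 h 39 genes were called, and at 48 h 138 were higher and 72 lower. With size factors in place of the authors' scaling, 291 genes were higher and 323 lower in the mean, and 89 and 85 at 48 h. The total of 706 was 74 in a fit of the compared groups alone, where the 210 genes at 48 h became 3, and it also changed with single libraries. It was 89 without the FR library at 30 h replicate 3, 117 without the FR library at 48 h replicate 4 and 168 without the 12 libraries whose expression went against a label, as described at the end (13 at 48 h alone). Leaving out the WL libraries at 30 h replicates 1, 2, 3 or 4 gave 356, 1110, 433 or 433, the FR library at 48 h replicate 2 gave 436 and the WL library at 48 h replicate 6 gave 370.

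**Figure D3:**
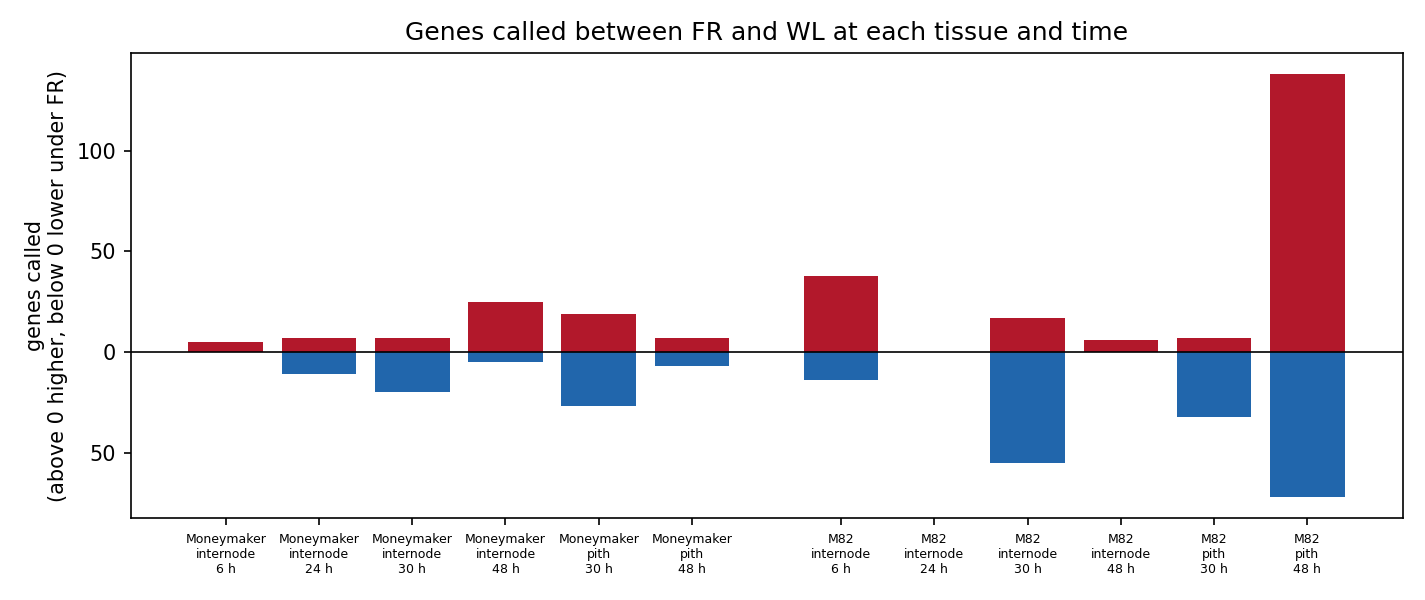
Number of genes called between FR and WL (bars, red above 0 for higher and blue below 0 for lower under FR) for each cultivar, tissue and time. M82 pith at 48 h had the most, with 138 higher and 72 lower genes, and M82 internodes at 24 h had 0.

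The far-red response of pith overlapped that of the internode, which contains pith. In Moneymaker, 28 higher and 42 lower genes were called in both tissues, where independent lists would share 0.26 and 0.52. In M82 the numbers were 46 and 48, against 1.3 and 1.1. Between cultivars, 30 of the 35 genes higher in Moneymaker pith were called higher in M82 pith, and all 35 had the same sign there. Of the 61 lower genes, 32 were called lower in M82 pith and 60 had the same sign. The whole lists had median log2 fold changes of 1.74 and -1.06 there. The 433 genes higher in M82 pith had a median of 0.271 in Moneymaker pith, where 30 were called higher (camera adjusted p = 0.04 with an estimated correlation). The 273 lower genes had a median of -0.401, with 32 called lower (adjusted p = 3e-04 with an estimated correlation). Without the 12 libraries that went against a cultivar or time label, the M82 pith lists held 66 higher and 102 lower genes, with medians of 0.888 and -0.717 in Moneymaker pith, where 24 and 25 were called. In Moneymaker internodes the 433 genes had a median of 0.186, and that list's call was lost with an estimated correlation (adjusted p = 0.091). The 273 genes had a median of -0.23 there, with 55 called lower (adjusted p = 0.001 with an estimated correlation).

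A core of 23 genes was called higher and 25 lower under FR in both tissues of both cultivars. All 9 genes named for the 4 means belong to it, 4 higher and 5 lower. Of these 9, Solyc02g085020 had the lowest fold change in pith of both cultivars and Solyc12g088170 in internodes of both, with -3.44 ± 0.41 in Moneymaker and -3.66 ± 0.45 in M82. Over the 4 means, 521 genes were called higher and 410 lower in at least 1, and 0 genes were called in opposite directions.

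Tests of differences between far-red effects called few or no genes. The FR effect differed between cultivars for 0 genes in internodes with limma, with 496 at an unadjusted p below 0.05 and 0 by both DESeq2 and edgeR. In pith it was 0 genes with limma, with 1412 at an unadjusted p below 0.05, 2 by DESeq2 and 0 by edgeR. Between pith and internode the FR effect differed for 0 genes in Moneymaker (740 at an unadjusted p below 0.05, 3 by DESeq2, 0 by edgeR). In M82 it was also 0 (1587 at an unadjusted p below 0.05, 0 by DESeq2 and edgeR). No gene passed the limma test between cultivars in pith, although 706 genes were called under FR in M82 pith and 96 in Moneymaker pith. These tests used the labels as given, and 6 libraries labelled M82 and 3 labelled Moneymaker expressed the other cultivar's genes, as described at the end. Their median SE over genes was 0.301 to 0.424, against 0.202 to 0.307 for the FR means. A count of 0 therefore does not show that the effects were equal.

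Pith differed from the whole internode in both cultivars, mostly through genes that were lower in pith. In Moneymaker 88 genes were higher and 126 lower in pith (14 and 17 libraries), and in M82 51 were higher and 469 lower (14 and 15 libraries). In Moneymaker, Solyc05g006850 was 1.02 ± 0.15 and Solyc11g012930 1.2 ± 0.23 higher in pith (adjusted p = 5.6e-05 and 0.003). Solyc02g085870 was lower by -1.39 ± 0.21 and Solyc02g071710 by -1.01 ± 0.16 (adjusted p = 5.3e-05 and 0.00016). In M82, Solyc01g109180 was lower in pith by -1.36 ± 0.17 and Solyc02g082930 by -1.71 ± 0.22 (adjusted p = 1.3e-07 and 5.4e-07). Solyc11g069540 was 1.3 ± 0.31 and Solyc12g010110 1.29 ± 0.32 higher (adjusted p = 0.005 and 0.0088), and both lost their call without the M82 FR pith library at 30 h replicate 3 (adjusted p = 0.067 and 0.055). Without that library 226 genes were called in M82, and without the Moneymaker FR pith library at 48 h replicate 4 132 were called in Moneymaker.

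The tissue lists of the cultivars overlapped, with 10 higher and 97 lower genes called in both against 0.24 and 3.1 for independent lists. Of the 126 genes lower in Moneymaker pith, 125 had the same sign in M82. The lists of genes lower in pith were also tested under FR. The 469 genes lower in M82 pith had a median log2 fold change of -0.574 between FR and WL in Moneymaker pith, with 23 called lower and 0 higher by limma (camera adjusted p = 0.001 with an estimated correlation). The library labelled Moneymaker FR pith at 48 h replicate 3 expressed M82 genes, as described at the end, and this list was not tested without it. In the reverse test, the 126 genes lower in Moneymaker pith had a median of -0.203 in M82 pith, with 6 called lower (camera adjusted p = 0.00067 with the preset correlation, adjusted p = 0.4 with an estimated correlation). In Moneymaker internodes the 469 genes had a median of -0.0413 (camera adjusted p = 0.051, and 0.02 with a replicate block). The 51 genes higher in M82 pith had a median of -0.129 in Moneymaker pith (camera adjusted p = 0.34). The 88 genes higher in Moneymaker pith had a median of -0.136 under FR in M82 internodes (camera adjusted p = 2e-05, and adjusted p = 0.27 with an estimated correlation).

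Between the cultivars as labelled, Moneymaker was higher than M82 for 5 genes and lower for 1 in white light internodes (13 and 15 libraries). Of these libraries, 2 labelled Moneymaker and 4 labelled M82 expressed the genes of the other cultivar. Solyc09g009550 was 1.79 ± 0.34 and Solyc06g071580 1.11 ± 0.22 higher in Moneymaker, and Solyc02g069290 differed by -0.79 ± 0.16 (adjusted p = 0.028 for each). None of the 3 was called by edgeR (adjusted p = 0.11, 0.07 and 0.068), which called 0 genes while 755 had an unadjusted p below 0.05 with limma and DESeq2 called 27. The replicate block gave 28 genes, the count ran from 0 to 49 with single libraries left out, and 166 were called, 53 higher and 113 lower in Moneymaker, without the 12 libraries whose expression went against a cultivar or time label. That last count is partly circular, since cultivar differences chose most of the libraries left out. With libraries chosen on odd chromosomes or on even ones and genes tested on the others, calls went from 18 to 121 and from 2 to 60.

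Time of day separated expression in both cultivars. Plants at 6 and 30 h after the start were at 1 clock time and plants at 24 and 48 h at another. In white light internodes of Moneymaker, 233 genes were higher at 6 and 30 h and 272 higher at 24 and 48 h, and in M82 389 and 566. Solyc01g100230 was higher at 6 and 30 h by 3.08 ± 0.36 in Moneymaker and 3.47 ± 0.34 in M82 (adjusted p = 1.2e-08 and 2e-11). Solyc10g005080 was lower then by -4.24 ± 0.47 and -4.62 ± 0.44 (adjusted p = 8.4e-09 and 2e-11). In Moneymaker, Solyc10g078920 was 2.82 ± 0.37 higher and Solyc07g063120 differed by -2.22 ± 0.27 (adjusted p = 2.2e-07 and 2.3e-08). In M82, Solyc03g116670 was 2.14 ± 0.24 higher and Solyc07g019460 differed by -1.95 ± 0.21 (adjusted p = 7.2e-10 and 3.2e-10). Both lists overlapped, with 195 and 223 genes called in both cultivars against 4.8 and 8.1 for independent lists, and effects correlated with r = 0.659 across genes. The Moneymaker count was 789 without the WL library at 48 h replicate 1 and 263 without the WL library at 6 h replicate 5. The M82 count was 480 and 599 without the WL libraries at 24 h replicates 2 and 1.

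The time-of-day lists had small median changes under far-red light. In M82 pith the 233 Moneymaker genes higher at 6 and 30 h had a median log2 fold change of -0.213 under FR, with 15 called lower, and the 272 genes higher at 24 and 48 h had a median of 0.264, with 12 called higher. Both calls were lost with an estimated correlation (adjusted p = 0.4 for each). Of the 5 WL libraries of M82 pith at 48 h, replicates 6 and 5 lay at time-of-day positions of 1.1 and 0.51. Such libraries move both medians in the direction seen, and the lists were not tested without them. In Moneymaker internodes the 389 M82 genes higher at 6 and 30 h had a median of -0.0554 and the 566 higher at 24 and 48 h one of 0.0657 (camera adjusted p = 0.061 and 0.086, and 0.0026 and 0.011 with a replicate block). Here too 1 of the 4 WL libraries at 48 h, replicate 1, lay at a time-of-day position of 1.04, which moves both medians in the direction seen. In M82 internodes the 272 genes had a median of -0.0587 (camera adjusted p = 0.33, and 0.014 with the block).

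Some libraries did not express the genes of their own label. Each library was placed between its own label (0) and the other label (1) by 100 genes per side for cultivar, time of day and light. For cultivar, 9 libraries lay at 0.91 to 1.1 and all others at 0.4 or below. Of these 9, 6 carry M82 white light labels: internodes at 6 h replicates 1 and 5, at 24 h replicate 1 and at 30 h replicate 1, and pith at 30 and 48 h replicate 1. The other 3 carry Moneymaker labels with replicate number 3: FR pith at 48 h, WL internodes at 30 h and WL internodes at 48 h. For time of day, the libraries labelled WL Moneymaker internode at 48 h replicate 1 and WL M82 pith at 48 h replicate 6 lay at 1.04 and 1.1, the one labelled WL M82 pith at 48 h replicate 5 at 0.51, and all others at 0.15 or below. For light, the library labelled FR M82 internode at 24 h replicate 3 lay at 0.99, the one labelled WL M82 internode at 30 h replicate 1 at 1.19, and all others at 0.31 or below. Without the first 12 of these libraries, 313 genes were called under FR in Moneymaker internodes, 112 in its pith and 127 in M82 internodes. All labels were kept as given.

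**Figure D4:**
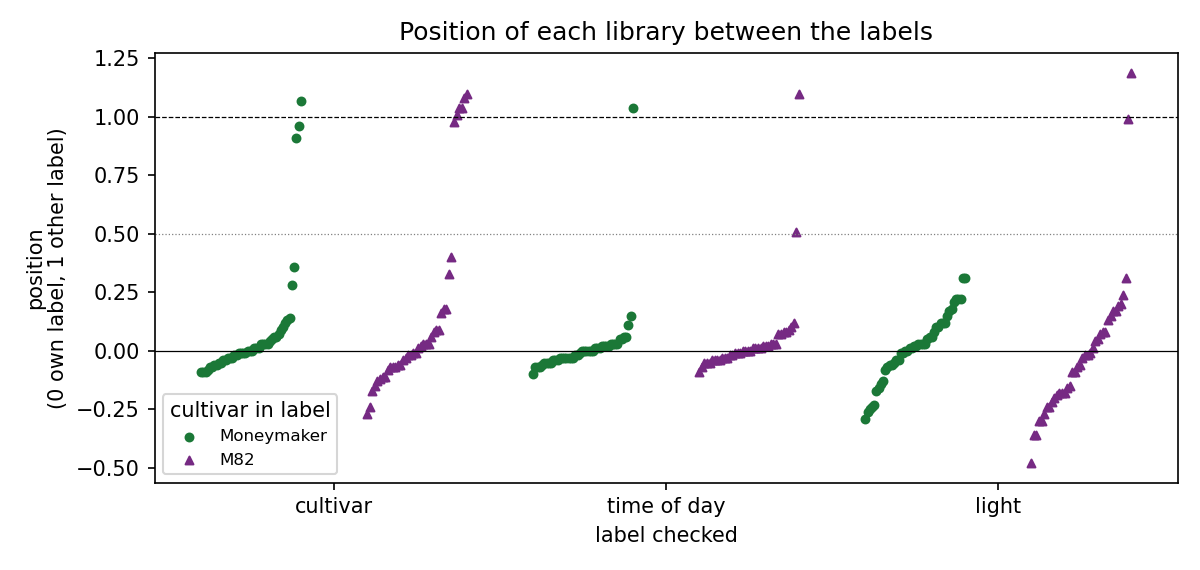
Position of each library (points, sorted within cultivar) between its own label at 0 and the other label at 1 for cultivar, time of day and light, green circles for libraries labelled Moneymaker and purple triangles for M82. The 9 libraries past the middle for cultivar lie at 0.91 to 1.1, and for light 2 libraries lie at 0.99 and 1.19.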

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

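All tests of label positions, of other splits of the libraries and of explanations in this part were chosen after the results were seen. For mislabelling and library composition in M82 pith, only the bounds were set before those tests were run. The outlier test and the test between times were planned. In groups of 4 to 6 libraries, 11 of 60 tests of a group and measure had 1 library far from the others, where chance gives about 1 in 20.

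For cultivar position, where 0 is the library's own label and 1 the other, these were the libraries labelled M82 WL internode 30 h replicate 1 at 0.98 (nearest other 0.09) and M82 WL pith 48 h replicate 1 at 1.04 (nearest 0.08). The Moneymaker ones were FR pith 48 h replicate 3 at 1.07 (nearest 0.12), WL internode 30 h replicate 3 at 0.96 (nearest 0.09) and WL internode 48 h replicate 3 at 0.91 (nearest 0). For time-of-day position they were the libraries labelled Moneymaker WL internode 48 h replicate 1 at 1.04 (nearest -0.01) and 30 h replicate 3 at 0.01 (nearest 0.02), the latter an outlier by a very small distance. The library labelled M82 WL internode 30 h replicate 1 also stood apart in light position, at 1.19 (nearest -0.02), and in light score, at 0.82 (nearest -1.06). In depth, M82 WL internode 6 h replicate 3 had 12.9 M reads (nearest 2.88) and Moneymaker FR internode 48 h replicate 4 had 22.1 M (nearest 4.74). The FR effect in M82 internodes differed between times for Solyc05g053530 (adjusted p = 0.00025) and Solyc02g089350 (adjusted p = 0.0012).

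The first pattern is that 9 libraries expressed the genes of the other cultivar. A mixture with RNA of the labelled cultivar is argued against by the 9 libraries' lowest position on the genes high in their own label, 0.96, close to the whole distance, while other libraries reached at most 0.38. On genes high in the other label, the 9 lay between 0.8 and 1.24. Among libraries kept, Moneymaker FR internodes at 48 h replicates 8 and 7 lay at 0.66 and 0.5 on such genes. M82 FR internodes at 48 h replicate 4 lay at 0.52. On the genes high in their own label these were at -0.03, -0.02 and 0.29. A partial mixture in them was not tested. For the 9 libraries, wrong cultivar labels may be the cause. When libraries were chosen by genes on odd or even chromosomes and tested on the others, calls between the cultivars rose from 20 with all libraries to 181 without the chosen ones. Odd chromosomes chose 10 libraries and even ones 9. The rise does not tell wrong labels from other causes that act on genes of all chromosomes. An event shared by a batch of plants also stays open: 5 of the 9 share M82, white light and replicate number 1, a set of 6 libraries, and as large a group arose with a shuffle p of 0.00013, while the 3 Moneymaker ones all have number 3 and only 2 of the 9 have a partner out of place in the same tissue, time and light.

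The second pattern is that 3 libraries labelled 48 h expressed the genes of 6 and 30 h. For the 2 libraries past 0.75, Moneymaker WL internode replicate 1 and M82 WL pith replicate 6, a wrong time label may be the cause, since both gene sets lay at 0.86 or above. For M82 WL pith replicate 5, a mixture and a harvest at another clock time cannot be told apart. Its excess of genes high at the other time over genes high at its own was 0.31, and other libraries reached the same excess of 0.31. No biological explanation was tested.

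The third pattern is that FR changed 706 genes in M82 pith and 96 in Moneymaker pith. Wrong labels stay open: leaving out the 4 doubted WL pith libraries of M82 gave 117 genes, below the median of 316 over the 40 ways of leaving out as many per time (range 90 to 2887), and 6 of these ways gave as few, a share past the bound of 0.05 set beforehand against wrong labels, but that bound was wrong by design, since any 3 of the 5 WL libraries at 48 h include at least 1 of the 3 doubted ones, so that each way also leaves out a doubted library. Single libraries could set the number, since 89 genes were called without the FR library at 30 h replicate 3. Library composition may also add to it, since with the first principal component in the fit the counts were 182 in M82 and 149 in Moneymaker. Of the 706 genes 618 had the same sign in Moneymaker pith, with a median log2 fold change in the M82 direction of 0.317 there against 0.967 in M82. The genes were chosen by their calls in M82 pith, which raises the M82 median, so these 2 medians do not show a cultivar difference. Such a difference stays open, as 0 genes passed its test with limma (1412 at an unadjusted p below 0.05, 2 by DESeq2 and 0 by edgeR).

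Other splits of the libraries into groups of the same sizes were refitted and their calls counted. Over all such splits, whatever the replicate numbers, a share under 0.05 gave as many calls as the real one for each of the 4 means over times. With at most 100 splits and no adjustment over the comparisons, this argues against chance without excluding it. Moneymaker internode had 1 of 100 splits as large (302 genes, highest other 82), Moneymaker pith 1 of 100 (96, highest other 20), M82 internode 2 of 100 (136, highest other 494) and M82 pith 2 of 100 (706, highest other 1058). The share was also under 0.05 for Moneymaker internodes at 24 h (2 of 56 splits, 18 genes, highest other 50), 30 h (1 of 35, 27 genes, highest other 22) and 48 h (1 of 100, 30 genes, highest other 10). So it was for Moneymaker pith at 30 h (1 of 35, 46 genes, highest other 43) and 48 h (1 of 35, 14 genes, highest other 3), and for M82 internodes at 30 h (2 of 56, 72 genes, highest other 107) and 48 h (1 of 35, 6 genes, highest other 2).

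The replicate numbers mark batches of plants, and few of these splits part as many pairs of the same number as the real one. Among those that do, the share was under 0.05 for the Moneymaker pith mean, where the real split was the only 1 of 34 as large (highest other 20). For the other comparisons of light given so far these splits are too few for a share under 0.05. With the real one included, they number 2 for each internode mean (302 genes in Moneymaker and 136 in M82, highest other 0 in each) and 4 for the M82 pith mean (706, highest other 24). Moneymaker internodes have 16, 12 and 10 of them at 24, 30 and 48 h (18, 27 and 30 genes, highest others 0, 22 and 0), and Moneymaker pith 20 at each time (46 and 14 genes, highest others 43 and 3). M82 internodes have 8 at 30 h and 8 at 48 h (72 and 6 genes, highest others 22 and 0).

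The splits do not argue against chance for M82 internodes at 6 h, where 5 of 35 splits gave as many genes as the real 52 and the highest other gave 2494 (95 genes with the replicate block). Of the 8 splits there that part as many pairs of the same replicate number, 2 gave as many, again with a highest other of 2494. The same holds for M82 pith at 48 h, with 4 of 56 splits, 210 real genes and a highest other of 984. Of the 8 splits there that part as many pairs, only the real one gave as many and the highest other gave 3, and 8 splits are too few for a share under 0.05. Some splits called several times the real number in these comparisons and in the M82 internode mean, and the cause was not tested. Over all splits, a share under 0.05 gave as many calls for pith against internode in Moneymaker (1 of 100, 214 genes, highest other 11) and M82 (1 of 100, 520, highest other 9), for cultivar (1 of 100, 6, highest other 1), and for clock time in Moneymaker (2 of 100, 505, highest other 701) and M82 (1 of 100, 955, highest other 579). Of these splits, 3, 1, 2, 13 and 2, in that order and with the real one included, part as many pairs, too few for a share under 0.05, and the highest others among them were 0, none, 0, 1 and 0. For interaction tests with 0 genes called by limma, all 100 splits necessarily gave as many, so the splits decide nothing there. Their highest other counts were 1 and 122 for cultivar by light in internode and pith, 5 and 70 for tissue by light in Moneymaker and M82, and 38 for time by light in Moneymaker. These tests had 496, 1412, 740, 1587 and 596 genes at an unadjusted p below 0.05, with 0, 2, 3, 0 and 0 by DESeq2 and 0 in each by edgeR. For time by light in M82, 13 of 100 splits gave at least the real 2 genes, with a highest of 380, so chance cannot be excluded for that count. Splits were not run for Moneymaker internodes at 6 h, M82 internodes at 24 h and M82 pith at 30 h, where a group held 2 libraries.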

How the results depend on the processing

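The edgeR test on recovered reads, the pseudocount, the runs without doubted libraries and the clock-time comparison were chosen after the results were seen. On counts, edgeR had been planned as the main test. The other alternatives were planned. None of the 35 values of named genes changed direction. All 35 kept their call with DESeq2, size factors, no filter, the replicate block and without 12 libraries, 32 with edgeR, 31 in fits of the compared groups alone and 34 with a pseudocount of 0.25, and of the runs that left out 1 library 746 kept the call and 34 lost it. Size factors moved none of the 27 counts by over 1.5 times. Simulated reads at the real depths carried changes in the more highly expressed genes. Of these, 1% of genes changed 2-fold and 51% of genes changed 4-fold were recovered in M82 internodes at 24 h, against 77% and 100% in the Moneymaker internode mean. In that group 1 of the 2 FR libraries, labelled replicate 3, lay at light position 0.99, and limma's 0 genes (710 at an unadjusted p below 0.05, 1 by DESeq2, 0 by edgeR) became 20 without replicate 2 and 1 without replicate 3. The cause of the shifts below was not tested. Runs that leave libraries out and fits of the compared groups alone also use fewer libraries.

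With DESeq2, Moneymaker internode counts went from 5 to 20 at 6 h, 18 to 36 at 24 h, 30 to 54 at 48 h and 302 to 465 in the mean, and pith from 46 to 73 at 30 h and 14 to 28 at 48 h. M82 internodes went from 52 to 362 at 6 h, 0 to 1 at 24 h, 72 to 114 at 30 h, 6 to 21 at 48 h and 136 to 236 in the mean, and pith at 48 h from 210 to 599. Cultivar by light in pith went from 0 to 2, tissue by light in Moneymaker from 0 to 3, time by light in M82 from 2 to 18, pith against internode in Moneymaker from 214 to 401 and cultivar from 6 to 27. With edgeR the counts were 8 and 16 in Moneymaker internodes at 30 and 48 h, 23 in its pith at 30 h, 10 in M82 pith at 30 h, 1 for time by light in M82 and 0 for cultivar. For these 0 genes, limma had 755 at an unadjusted p below 0.05 and called 6, and DESeq2 called 27.

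With no filter, Moneymaker internodes at 6 h had 8 genes, tissue by light in Moneymaker 1 and time by light in Moneymaker 2. In fits of the compared groups alone, Moneymaker internodes had 27, 37 and 17 at 6, 24 and 48 h. M82 internodes had 5 and 59 at 30 and 48 h, and M82 pith 6, 3 and 74 at 30 h, 48 h and in the mean. Time by light in M82 had 0 and cultivar 0 with limma (1457 and 755 at an unadjusted p below 0.05 in the fit of all groups, where edgeR called 1 and 0). The counts were 114 for pith against internode in Moneymaker and 262 for clock time in Moneymaker. With a pseudocount of 0.25, M82 pith at 30 h had 61, time by light in M82 1 and cultivar 2.

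The replicate block gave 8 and 52 genes in Moneymaker internodes at 6 and 48 h, 95 and 10 in M82 internodes at 6 and 48 h, 1 for time by light in Moneymaker and 28 for cultivar. It changed the calls of 4 list tests, given with the results, and of no other list, and it moved no other count by over 1.5 times, though the genes called were not all the same (80 of the 96 in Moneymaker pith and 687 of the 706 in M82 pith). Of the 32 list tests, 21 passed with camera's preset correlation, 16 with an estimated one, 25 with the block and 17 with fry.

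Without the 12 libraries that went against a cultivar or time label, Moneymaker internodes had 19, 29, 46 and 6 genes at 6, 24, 30 and 48 h, and pith at 30 h 80. M82 internodes had 27, 259 and 14 at 6, 30 and 48 h, and M82 pith 13 at 48 h and 168 in the mean, 66 higher and 102 lower. The 12 include the WL library of M82 internodes at 30 h replicate 1, which also lay at light position 1.19. Leaving out that library alone moved the M82 internode count at 30 h from 72 to 188. Time by light in M82 had 4, pith against internode in Moneymaker 125, cultivar 166 and clock time in M82 621. Without also the FR library of M82 internodes at 24 h replicate 3, chosen by its light response and so partly circular, Moneymaker internodes had 29, 32, 53 and 7, and pith 90 and 23 at 30 and 48 h. M82 internodes then had 31, 5, 280 and 18, M82 pith 32 at 48 h and 196 in the mean, and time by light in M82 5.

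With each library left out in turn, Moneymaker internodes ran from 0 to 7 at 6 h, 5 to 23 at 24 h, 0 to 74 at 30 h, 10 to 54 at 48 h and 161 to 371 in the mean. Moneymaker pith ran from 14 to 43 at 30 h, 2 to 15 at 48 h and 54 to 107 in the mean. M82 internodes ran from 28 to 1073 at 6 h, 0 to 20 at 24 h, 29 to 188 at 30 h, 3 to 8 at 48 h and 68 to 187 in the mean. M82 pith ran from 1 to 369 at 30 h, 17 to 473 at 48 h and 89 to 1110 in the mean. Cultivar by light ran from 0 to 0 in internodes and 0 to 1 in pith, tissue by light from 0 to 0 in Moneymaker and 0 to 3 in M82, and time by light from 0 to 1 in Moneymaker and 2 to 7 in M82. Pith against internode ran from 132 to 267 in Moneymaker and 226 to 729 in M82, cultivar from 0 to 49, and clock time from 263 to 789 in Moneymaker and 480 to 1101 in M82. Where this left 1 library in a group, that library was assumed to vary like the other groups.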

Other observations

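The tests in this part were all chosen after the results were seen. Genes that differed between the cultivars lay unevenly over the genome. Without the 12 libraries that went against a cultivar or time label, 166 genes differed in white light internodes, 53 higher and 113 lower in Moneymaker. By the chromosome number in the identifier, chromosome 4 held 34 of them among 1583 genes tested (2.15%) and chromosome 12 held 21 among 1239 (1.69%), while chromosome 7 held 4 among 1368 (0.292%).

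The called genes also sat next to each other. In the order of the identifiers, 24 pairs of neighbouring tested genes were both called between cultivars, against 1.45 expected from 10000 shuffles, a ratio of 16.5 (permutation p = 1e-04, the smallest possible). A candidate explanation is that the cultivars differ by blocks of divergent sequence, so that neighbouring genes differ in expression or in how well their reads map. The ratio was 3.53 for the genes called under FR in Moneymaker internodes (17 pairs against 4.81 expected, p = 1e-04) and 1.24 for those between pith and internode in Moneymaker (3 against 2.42, permutation p = 0.43). Neighbouring copies of 1 gene family could give such pairs too, and this was not tested. The 166 genes were called after leaving out libraries chosen on the same cultivar differences.

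Over all libraries, the first principal component held 20.9% of the variance, of which group explained 32.6%, and it correlated with the sum of values per library (r = -0.791). The second component held 12.3%, and the clock time of harvest explained 82.9% of it. The third held 6.37%.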
